A study of Homo sapiens with 16 samples.

How the data were processed

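RNA from 16 cultures of human breast cancer cell lines was hybridised to 16 single-colour (Cy3) Agilent 44K whole-genome expression arrays. BT-20 and MDA-MB-231 are established breast carcinoma lines. Each of the 4 groups held 4 arrays, which the series' design text describes as independent experiments. BT-20 cells infected with a retrovirus carrying the CapG coding region were set against BT-20 controls. MDA-MB-231 cells transfected with 15 nM of a CapG siRNA were set against MDA-MB-231 controls. The design text calls the controls untreated. The protocol of the BT-20 work also names an empty vector, with cells carrying either vector selected in 1 mg/ml G418, and it is not settled whether the BT-20 controls carried it. If they did not, infection and G418 go wholly with the CapG group. The siRNA protocol names a transfection reagent and the CapG siRNA, and no control siRNA, and whether the MDA-MB-231 controls received the reagent is not stated.

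Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.1.1.1, with spatial detrending and local background subtraction, and hold the processed intensity, the mean intensity and the local background intensity of 45015 spots per array. Per the file headers, probe coordinates were on build hg18. The deposited value table of the authors is on a log2 scale. Comparison with the scanner files showed the log2 processed signal scaled to the 75th percentile of each array, with each probe centred on its median over the 8 arrays of its line, so that table cannot compare the lines and was used only as an alternative.

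From the scanner files, log2 processed intensity minus the array's 75th percentile was computed. Control spots and spots with an outlier mark were left out, and spots of a probe were averaged. Of 41000 probes, 28723 were named through the RefSeq gene table and 12277 kept the name in the file. A probe was tested when it was well above background on at least 3 of the 4 arrays of at least 1 group, and the brightest probe stood for its gene. Among genes with several such probes, the sign of another probe differed for 416 of 1586 called genes in BT-20 and for 187 of 1527 in MDA-MB-231. Each line was fitted alone with limma 3.58.1 in R 4.3.3, modified minus control, with two-sided Benjamini-Hochberg adjusted p-values and a threshold of 0.05. The difference between the lines was fitted on all 16 arrays, and the control lines were compared with slide as a random block. A gene whose probe was not well above background on every array of the dimmer group has only a bound there. Its fold is given as "at least", from the mean of the brighter group and, per array of the dimmer group that was not well above background, the higher of its own signal and the lowest signal well above background. Giving a bound also where some arrays of the dimmer group were well above background was chosen after seeing the data.

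The 35 gene lists, the designs and the rule for named genes were fixed before the data were examined. By that rule, not all of whose genes are given, the genes to name were CAPG, the 12 largest increases and the 12 largest decreases among symbol-named genes with an adjusted p under 0.05 and no overlap between the groups' arrays, and up to 4 members of each described list with the smallest adjusted p. Across the lines up to 8 genes per direction were named by the smaller of their changes, and for the control lines up to 5 members per described list with the largest difference. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation.

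The 16 arrays lay on 4 slides. Slides 1 and 2 held MDA-MB-231 arrays, slides 3 and 4 held BT-20 arrays, and each held 2 arrays of each group of its line. Slide 1 carried another protocol name in the file headers, the only one of 134 recorded settings that differed. The 75th percentile of the processed signal ran from 1200 to 3952 across arrays, and 59.1% to 77.2% of probes were well above background. The number of arrays limits the precision. No pair of arrays of a group was identical, the smallest SD of the difference between 2 arrays being 0.159 on the log2 scale.

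Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, a stricter filter, slide and replicate blocks, each slide alone, a fit of all arrays together, a mean-variance trend, the mean over probes, the authors' value table, a fold threshold and leaving out each array. The planned normexp fit failed on 5 arrays, as the closing section describes, and a repaired version was added after seeing the data.

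The tests were tested on simulated data, with arrays drawn from the real means and spreads and 200 changed genes. In the BT-20 simulation of 19419 genes, 50.7% of genes changed by 0.5 log2, 92.5% of those changed by 1 and 100% of those changed by 2 were called. In the MDA-MB-231 simulation of 21107 genes these shares were 0%, 19.4% and 68.2%. In the data 27.0% of genes were called in BT-20 and 24.3% in MDA-MB-231, far more than the 200 changed here. The adjusted p threshold is stricter when few genes change, so these shares do not carry over to the data.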

Results

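Expression of CAPG, an actin filament capping protein of the gelsolin family, had, by the labels, been raised in BT-20 cells and lowered in MDA-MB-231 cells, to ask which genes change with it. Each group had 4 arrays.

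In MDA-MB-231 cells the CAPG probe fell by 4.80 on the log2 scale after the siRNA (SE 0.25, n = 4 per group), 27.8-fold lower, with a limma adjusted p of 1.4e-05. Its normalized log2 level was 5.28 ± 0.37 (SD, n = 4) in controls and 0.48 ± 0.37 in siCapG cells. Within slides the difference was -4.69 on slide 1 and -4.90 on slide 2. In BT-20 cells the same probe was lower, not higher, in the arrays labelled CapG, at -0.16 ± 0.08 (SD, n = 4) against 0.46 ± 0.11 in controls. The difference was -0.63 (SE 0.07, limma adjusted p = 0.00067), with -0.65 on slide 3 and -0.61 on slide 4.

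The array has 1 CAPG probe, at chromosome 2, bases 85475420 to 85475479 of hg18 on the minus strand, with the sequence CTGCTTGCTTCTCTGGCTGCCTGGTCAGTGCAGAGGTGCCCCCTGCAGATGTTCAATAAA. It starts at base 1344 of the transcript and ends in a poly(A) signal. The construct held only the coding region, so a probe ending in the poly(A) signal would lie outside it. By that position it would read only the cell's own transcript, and it does not check the labels of the BT-20 arrays.

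**Figure D1:**
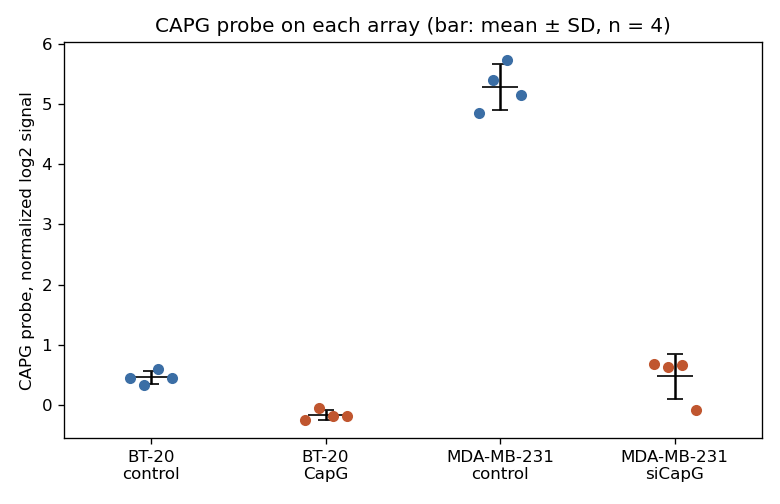
Normalized log2 signal of the CAPG probe (vertical axis) on each array by group (horizontal axis), points being arrays and bars the mean ± SD of 4 arrays. MDA-MB-231 controls averaged 5.28, while the means of the other groups lay between -0.16 and 0.48.

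In BT-20 cells the interferon-stimulated genes were lower in the CapG group. Of 34 tested members 29 fell and 1 rose (1 up and 30 down when adjusted over the list alone), with a median log2 fold change of -0.92. IFI44, an interferon-induced antiviral gene, fell by 4.57 (SE 0.13, n = 4 per group), IFI6 by 3.29 (SE 0.15), IRF9, part of the interferon signalling complex, by 2.94 (SE 0.14) and OASL fell by 2.23 (SE 0.10). The limma camera test gave an adjusted p of 7.1e-20 at the preset correlation, and the call was lost with adjusted p = 0.41 with an estimated correlation. Without CapG replicate 1, whose background was uneven, 30 members fell and 1 rose.

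Antigen presentation and lipid synthesis genes moved less in BT-20. In the MHC class I list 5 of 15 members fell and 0 rose (6 and 0 when adjusted over the list alone), with HLA-E at -0.32 (SE 0.05). Its camera adjusted p of 0.0047 from limma became adjusted p = 0.41 with an estimated correlation. In the fatty acid synthesis list 7 of 16 fell and 1 rose (7 and 1 when adjusted over the list alone), among them ACACA, which makes malonyl-CoA, at -0.62 (SE 0.12), and SCD at -0.38 (SE 0.08). Its limma adjusted p was 0.048, and again adjusted p = 0.41 with an estimated correlation, and the call was also lost with slide as a block.

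Other BT-20 lists did not pass the test. In the extracellular matrix list 9 of 20 genes rose and 2 fell (9 and 2 when adjusted over the list alone), with LAMB1 at 0.54 (SE 0.06) and fibronectin (FN1) at -1.29 (SE 0.07), and the camera adjusted p from limma was 0.062. In the gelsolin list 1 of 16 rose and 4 fell (1 and 5 when adjusted over the list alone), with gelsolin (GSN) at 0.32 (SE 0.06) and ADD3 at -0.47 (SE 0.07). In the cell cycle list 7 of 31 rose and 2 fell (7 and 2 when adjusted over the list alone), with KIF11 at 0.36 (SE 0.05), though its other probe moved by -0.15, and CCND1 at -0.43 (SE 0.08).

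Among the largest single increases in BT-20 CapG cells were those in NECTIN3, an adhesion molecule, by 3.25 (SE 0.06, 9.50-fold), in C19orf33 by 3.43 (SE 0.26) and in LSM14B by 2.99 (SE 0.38). Without any single CapG replicate another LSM14B probe was the brighter, with changes from 0.65 to 0.79. ADIRF rose by 2.65 (SE 0.08), SYTL5 by 2.62 (SE 0.21), the calcitonin receptor gene CALCR by 2.08 (SE 0.05) and MAT1A by 1.85 (SE 0.06). Bounds applied to MYRIP (at least 8.53-fold higher), CD86 (at least 3.52-fold), VAV1 (at least 2.86-fold), PSAT1 (at least 2.09-fold) and IL7 (at least 2.00-fold). The carboxypeptidase gene CPVL was at least 27.2-fold lower, RTN1 at least 6.89-fold, CFAP52 at least 4.30-fold, CCDC63 at least 2.83-fold and PCDHB17P at least 2.19-fold. PLA2G1B was at least 30.1-fold lower, IFI44L at least 19.2-fold and GLS2 at least 13.1-fold, and ARHGAP36 fell by 3.58 (SE 0.07). For all of these the limma adjusted p was under the threshold and the arrays of the groups did not overlap.

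In BT-20, 5252 of 19419 genes were called by limma, 3205 higher and 2047 lower (61.0% higher), and 334 of them changed at least 2-fold. Under the repaired normexp background correction 3115 genes were called and 72.0% of them were higher. Without control replicate 1 the count was 3360.

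In MDA-MB-231 cells genes of cell division fell together after the siRNA. In the cell cycle list 27 of 31 fell and 1 rose (28 and 1 when adjusted over the list alone), with a median log2 fold change of -2.34. KIF20A, a mitotic kinesin, fell by 3.39 (SE 0.20, n = 4 per group), the transcription factor FOXM1 by 3.14 (SE 0.20), cyclin A2 (CCNA2) by 2.84 (SE 0.16) and BIRC5 by 2.61 (SE 0.16). In the DNA replication list 25 of 27 fell and 0 rose (26 and 0 when adjusted over the list alone), with TYMS at -3.10 (SE 0.22), MCM10 at -2.96 (SE 0.17) and RRM2 at -2.84 (SE 0.16). The camera adjusted p values from limma were 1.6e-21 and 9.2e-18, and both calls held with an estimated correlation, also with slide as a block (adjusted p = 0.0049 for each). Within slides the cell cycle medians were -2.33 and -2.33, and the DNA replication medians -1.71 and -1.70.

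Actin-linked, integrin, TGF-beta target and interferon lists were also lower in siCapG cells and held with an estimated correlation. With slide as a block as well, only actin turnover (camera adjusted p = 0.031) and interferon genes (0.037) held among the 6 lists here. In the gelsolin list 10 of 17 fell and 0 rose (10 and 0 when adjusted over the list alone), with LCP1, an actin-bundling protein, at -2.78 (SE 0.25), GSN at -1.93 (SE 0.24) and FLII at -1.85 (SE 0.28). That list includes CAPG itself, and its median was -0.79, or -0.72 with genes not well above background at their bounds. In the actin turnover list 13 of 43 fell and 0 rose (16 and 0 when adjusted over the list alone), with TAGLN at -2.06 (SE 0.17) and the formin gene DIAPH3 at -2.05 (SE 0.19). In the SRF and MRTF target list 10 of 20 fell and 1 rose (12 and 1 when adjusted over the list alone), with ANKRD1 at -2.39 (SE 0.19) and CCN2 at 1.83 (SE 0.23). Caveolin 1 (CAV1) fell by 2.61 (SE 0.18) and ITGA3 by 1.94 (SE 0.24) in the integrin list, where 8 of 24 fell and 0 rose (8 and 0 when adjusted over the list alone). In the TGF-beta target list 9 of 19 fell and 0 rose (10 and 0 when adjusted over the list alone), and in the interferon list 11 of 34 fell and 2 rose (11 and 2 when adjusted over the list alone), with OAS3 at -2.36 (SE 0.17) and CXCL10 at least 3.86-fold higher. The camera adjusted p values of these 6 lists from limma lay between 5.0e-05 and 0.0014.

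Lists of cell identity and matrix passed at the preset correlation only. In the epithelial list 11 of 26 fell and 2 rose (14 and 2 when adjusted over the list alone), with E-cadherin (CDH1) at -2.94 (SE 0.29) and CLDN7 at -2.36 (SE 0.23), and adjusted p = 0.16 with an estimated correlation. In the mesenchymal list 8 of 24 fell and 2 rose (10 and 3 when adjusted over the list alone), with S100A4 at -2.72 (SE 0.28) and LOX at 1.07 (SE 0.19), and adjusted p = 0.11 with an estimated correlation. In the extracellular matrix list 13 of 26 fell and 6 rose (14 and 7 when adjusted over the list alone), with LUM at least 7.24-fold lower and COL1A1 at 2.30 (SE 0.23), and adjusted p = 0.16 with an estimated correlation. In the matrix protease list 8 of 26 fell and 1 rose (8 and 1 when adjusted over the list alone), with MMP13 at least 5.38-fold lower and ADAMTS1 at 1.96 (SE 0.31), and adjusted p = 0.069 with an estimated correlation. Among NRF2 targets 8 of 26 fell and 1 rose (8 and 1 when adjusted over the list alone), with AKR1C3 at -2.86 (SE 0.29) and NQO1 at -2.37 (SE 0.23), and adjusted p = 0.21 with an estimated correlation. In the cholesterol list 9 of 23 fell and 1 rose (10 and 1 when adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). In the fatty acid list 8 of 16 fell and 0 rose (9 and 1 when adjusted over the list alone; adjusted p = 0.069 with an estimated correlation).

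The remaining lists that passed at the preset correlation only were MHC class I (0 up and 3 down of 16, both ways of adjusting; adjusted p = 0.37 with an estimated correlation), growth factors and their receptors (2 up and 9 down of 26, or 2 and 10 when adjusted over the list alone; adjusted p = 0.16 with an estimated correlation) and metastasis suppressors and S100 proteins (3 up and 7 down of 22, or 3 and 8 when adjusted over the list alone; adjusted p = 0.44 with an estimated correlation). B2M, the light chain of MHC class I, fell by 0.59 (SE 0.17), EGFR by 1.42 (SE 0.19) and S100A2 by 2.84 (SE 0.29). Endothelial markers (0 up and 4 down of 6, both ways of adjusting; adjusted p = 0.13 with an estimated correlation) included PECAM1, an adhesion molecule. Oxidative phosphorylation genes shifted up with a median of 0.42, though 1 of 29 rose and 1 fell by either adjustment (adjusted p = 0.63 with an estimated correlation). Of the 20 lists that passed, 8 held with an estimated correlation. These were named in the paragraph on cell division and in that opening with actin-linked lists. With slide as a block, 4 of the 8 held, and the gelsolin (adjusted p = 0.055), integrin (0.061), TGF-beta (0.061) and SRF and MRTF (0.10) lists did not. The sign of median, mean and test differed for NF-kB targets, RNA interference genes and packaging line markers in MDA-MB-231. In BT-20 it differed for the lists of actin turnover, matrix proteases, NF-kB, immediate early, TGF-beta, Wnt, growth factor and NRF2 genes, none of which passed.

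**Figure D2:**
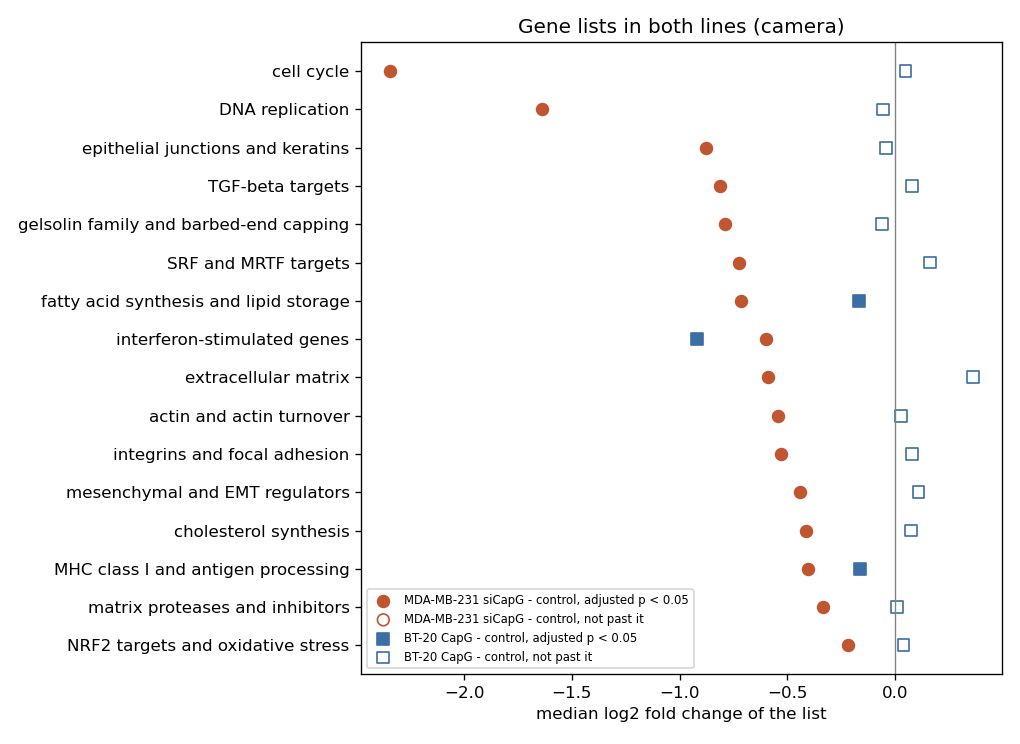
Median log2 fold change of each described gene list (horizontal axis) in BT-20 CapG minus control (squares) and MDA-MB-231 siCapG minus control (circles), filled where the camera adjusted p was under 0.05 at the preset correlation. The cell cycle list was at -2.34 in MDA-MB-231 and 0.05 in BT-20.

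Among single genes, LRRC73 rose by 4.42 (SE 0.22, 21.3-fold) in siCapG cells, SPON2 by 4.11 (SE 0.25) and RSPH1 by 3.48 (SE 0.19). The cancer-testis antigen gene CTAG1A, which has a near-identical copy, was 16.1-fold higher. FAM78A rose by 2.93 (SE 0.32), and BSN was at least 3.63-fold higher. LYRM9 rose by 3.58 with a larger SE of 0.91, and by 2.52 without control replicate 1, its lowest control. Its adjusted p was 0.051 without siCapG replicate 1 and 0.050 without siCapG replicate 2 (limma). NEGR1 was at least 3.75-fold higher, SLIRP-OT1 at least 2.93-fold, ZNF385D at least 2.81-fold, TNFSF18 at least 2.41-fold and CFAP210 at least 2.32-fold. ANXA8L1, one of several near-identical annexins, fell by 4.67 (SE 0.20), the scavenger receptor gene MARCO by 4.28 (SE 0.23) and CDA by 3.86 (SE 0.32). PLEKHS1 was at least 21.0-fold lower, SLC16A12 at least 10.6-fold and ALDH3A1 at least 10.4-fold. FANCD2, a DNA repair gene, was at least 12.2-fold lower by its tested probe, whose fitted change was -4.15, or -3.15 without siCapG replicate 2. Another FANCD2 probe, well above background on every array, fell less, by 2.86. ST6GALNAC5 was at least 11.5-fold lower, DENND2D at least 7.58-fold, PTGS1 at least 4.62-fold (fitted change -4.35) and ADAM28 at least 4.50-fold. Without control replicate 4 the other probe of PTGS1 was the one tested, with a change of -3.55. All of these passed the limma threshold.

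In MDA-MB-231, 5129 of 21107 genes were called by limma, 2102 higher and 3027 lower (41.0% higher), and 3159 changed at least 2-fold. Slide 1 alone gave 675 genes and slide 2 alone 9307. With slide as a block the count was 7425.

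The lines were then compared in their response, each taken from lower to higher CAPG by label. The responses differed for 5984 of 21931 genes (limma interaction term, which rests on the direction of the BT-20 labels). Line goes wholly with the kind of change, a retroviral construct in BT-20 and an siRNA in MDA-MB-231. A difference between the lines therefore cannot be told apart from one between the methods or between the sizes of their change in CAPG. Of 18595 genes tested in both lines, 1414 were called in both, 739 of them moving with the CAPG label and 675 against it. Genes higher in BT-20 CapG and lower in MDA-MB-231 siCapG numbered 541, where independent lists would share 399 (Fisher's exact test across genes, odds ratio 1.55, p = 1.2e-15). Genes lower in BT-20 CapG and higher in MDA-MB-231 siCapG, the other direction with CAPG, numbered 198 against 183 (odds ratio 1.1, exact p = 0.234), so that part was not enriched. Against CAPG, genes lower in both numbered 339 against 253 (odds ratio 1.48, exact p = 2.9e-09) and genes higher in both 336 against 290 (odds ratio 1.22, exact p = 0.0021). Genes are not independent replicates. Sharing exceeded that of independent lists both with CAPG (541) and against it (339 and 336), so these tests do not show that genes follow CAPG. Across genes the log2 fold changes, each taken from lower to higher CAPG by label, had a Pearson r of -0.10 and a Spearman rho of -0.09. The sign is that of a weak tendency against the CAPG label.

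TGFB2, a TGF-beta ligand, rose by 1.61 (SE 0.07) in BT-20 CapG cells and fell by 2.45 (SE 0.44) in MDA-MB-231 siCapG cells. CAPN8 moved by 1.77 and -1.78, ADIRF by 2.65 and -1.75, UNC13D by 1.69 and -1.62 (its other probe by 0.07 in MDA-MB-231), FHL1 by 1.35 and -1.47, and GPNMB by 1.31 and -2.20. VEPH1 (1.58 in BT-20 and at least 3.07-fold lower in MDA-MB-231) and ADRA1B (at least 2.06-fold higher in BT-20 and -1.43 in MDA-MB-231) also passed limma's threshold in both lines. The VEPH1 call in MDA-MB-231 was lost without control replicate 1, 2 or 4 or siCapG replicate 2 or 3, with adjusted p from 0.064 to 0.11 (limma). The ADRA1B call in BT-20 was lost without CapG replicate 2, 3 or 4, with adjusted p from 0.053 to 0.060 (limma). Genes that fell in both lines included IFITM1 (-2.47 in BT-20 and -2.23 in MDA-MB-231), IRF9 (-2.94 and -1.72) and TIMP3 (-1.53 and -2.38). In BT-20 only bounds applied to AKR1C1 (at least 4.10-fold lower, and -3.54 in MDA-MB-231), IFI44L (at least 19.2-fold, and -2.03) and IFI27 (at least 5.18-fold, and -1.66). TDO2 fell by 1.75 in BT-20 and was at least 2.63-fold lower in MDA-MB-231, while AQP1 was at least 1.36-fold lower in BT-20 and fell by 1.70 in MDA-MB-231.

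**Figure D3:**
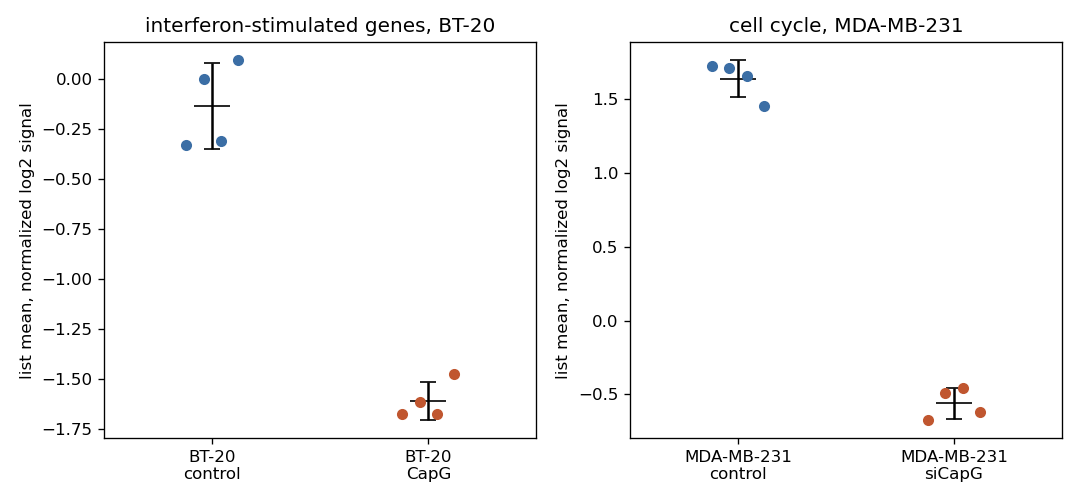
Mean normalized log2 signal (vertical axes) over the interferon-stimulated genes in BT-20 and over the cell cycle genes in MDA-MB-231 on each array by group (horizontal axes), points being arrays and bars the mean ± SD of 4 arrays. The interferon list lay between -0.33 and 0.09 in BT-20 controls and between -1.68 and -1.47 in CapG cells.

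The control lines differed at 13577 of 21365 genes (limma), 6054 higher in MDA-MB-231 and 7523 higher in BT-20. CAPG was 28.2-fold higher in MDA-MB-231 controls (log2 difference 4.82, SE 0.22, adjusted p = 1.6e-11). Of 24 mesenchymal genes 18 were higher in MDA-MB-231, among them vimentin (VIM) by 7.21 (SE 0.18) and AXL by 8.86 (SE 0.18). Of 28 epithelial genes 18 were higher in BT-20, with CDH1 at -6.43 (SE 0.24) and ESRP1 at -6.45 (SE 0.17). Of that list 6 were higher in MDA-MB-231, and its largest difference was that of the keratin gene KRT7, at least 359-fold higher there. Of 20 SRF and MRTF targets 19 were higher in MDA-MB-231, with CCN1 at 5.49 (SE 0.12). Of 27 DNA replication genes 23 were higher in BT-20, with GINS2 at -3.53 (SE 0.30). Each line lay on its own slides, which were taken as a random block.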

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

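The tests of a single array, of the uneven array, of slides, of scaling, of probe position, of exchanged labels, of the difference between the lines under exchanged labels and of the transfection were chosen after the result was seen. The tests of mixed cells and of gene dosage were not.

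The CAPG probe did not rise in the BT-20 arrays labelled CapG. It starts at base 1344 of the transcript and ends in a poly(A) signal, which is consistent with a probe outside the cloned coding region. Leaving out any of the 8 arrays gave a difference of -0.58 or lower, which argues against a single array. An exchange of the labels of the BT-20 groups cannot be told apart from the labelled design by the probe's difference of -0.63, because a probe at this position would not read the construct. A lower level of the cell's own transcript in cells carrying the construct remains an untested biological explanation.

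The interferon-stimulated genes were lower in BT-20 CapG cells. Without CapG replicate 1 the list median was -0.92, which argues against that uneven array. The 369 genes with a log2 excess of at least 6 in MDA-MB-231 controls had a median of -0.0046 in BT-20 CapG cells, which argues against MDA-MB-231 cells in those cultures. Of 34 interferon genes, however, 18 were higher and 10 lower in MDA-MB-231 than in BT-20 controls, with a median difference of 0.76. Mixed cells could therefore hardly lower this list, and their absence does not bear on its fall. The 520 neighbours of the interferon genes, on 16 chromosomes, had a median of 0.052 (SD 0.41), which argues against a changed dosage of those segments. Selection in 1 mg/ml G418, which goes with the CapG group if the controls were untreated, the viral infection, an outgrowth of cells with less interferon signalling and the construct itself may each contribute and were not tested. The direction rests on the BT-20 labels. An exchange of those labels, which the CAPG probe cannot exclude, would turn this fall into a rise.

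The cell cycle and DNA replication genes were lower in MDA-MB-231 siCapG cells. Their joint median was -1.98 on the slide where it was nearest to 0, which argues against the difference between slides. A factor per array moves all genes alike, yet relative to all genes it was -2.11 (SE between arrays 0.09) in the main fit. It was nearest to 0, at -1.88 (SE between arrays 0.07), under the repaired normexp correction, the failed fit left out, which argues against the scaling of the arrays as the whole cause. The labels name 0 arrays of a control siRNA and do not say whether the controls received the transfection reagent, so the transfection and the loss of CAPG cannot be told apart.

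Other splits of the same arrays were used to ask whether chance can be excluded. In BT-20 the real split was the highest of 35 with 5252 genes, the next giving 241 (1 of 35 splits as large). In MDA-MB-231 it was the highest of 35 with 5129 genes, and the next gave 848 (1 of 35). That next split put slide 1 against slide 2. A share of 1 of 35 is the smallest these splits can give, and they did not keep the slides. It argues against chance in both lines but does not exclude it. For lists, 10 of 35 splits in BT-20 gave at least the real 3, with up to 5 in another split, so chance was not excluded for the number of lists there. In MDA-MB-231 the real split gave 20 lists and the next 19 (1 of 35). For genes differing in response the real split gave 5984, the highest of the 100 drawn (1 of 100). The highest of the others gave 4893 and kept the real MDA-MB-231 groups. These splits regroup both lines and so also remove the change within each line. They cannot decide whether the lines respond differently beyond chance. For the control lines the values were 13577 in the real split and 0 in the highest of the others (1 of 35). Every other split puts arrays of both lines into each group, which widens the spread, so a low count was given in advance. These splits cannot decide on chance for the control lines, and each line lay on its own slides. For genes following CAPG in both lines the values were 739 and 0 (1 of 100). Other splits call few genes in either line, so this shows only that both lines have calls. It does not show that genes follow CAPG beyond chance, and 675 genes called in both lines moved against it.

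The responses of the lines, each taken from lower to higher CAPG by label, differed for 5984 genes in the limma interaction test. Line and method of changing CAPG go together, so neither can be named as the source. By list, the median difference of BT-20 from MDA-MB-231 was -2.24 for cell cycle, -1.65 for DNA replication, -1.91 for interferon-stimulated, -0.83 for fatty acid, -0.72 for gelsolin, -0.53 for actin turnover, -0.50 for integrin and -0.50 for TGF-beta genes, all past the threshold with an estimated correlation. These values add the changes of both lines. For cell cycle the medians were 0.05 in BT-20 and -2.32 in MDA-MB-231 siCapG cells. For DNA replication they were -0.05 and -1.64, so both differences came mostly from MDA-MB-231. For genes that fell in both lines the differences rest on the direction of the BT-20 labels. If those labels were exchanged, the change in BT-20 minus that in MDA-MB-231 would apply, up to its sign, and it passed for 5298 genes whose response differs between the lines. It was 2.42 for cell cycle, 1.5 for DNA replication, 0.66 for TGF-beta, 0.56 for integrin, 0.51 for actin turnover and 0.31 for gelsolin genes, past the threshold with an estimated correlation. It also passed for SRF and MRTF targets (0.89, adjusted p = 0.016 with an estimated correlation), which by the labels did not pass (-0.54, adjusted p = 0.063). It did not pass for interferon-stimulated (-0.51, adjusted p = 0.24 with an estimated correlation) or fatty acid genes (0.66, adjusted p = 0.14). Among genes named across the lines, differences past the threshold by the labels were -6.58 for IFI44L, -5.82 for AKR1C1, -4.70 for IFITM1, -4.66 for IRF9, -4.27 for AQP1, -4.16 for IFI27, -4.16 for TDO2, -3.91 for TIMP3 and -0.89 for GPNMB. For IFI44L, AKR1C1, AQP1, IFI27 and TDO2 these fitted values rest in part on arrays not well above background. Of these 9 genes all but GPNMB fell in both lines. The change in BT-20 minus that in MDA-MB-231 was -2.51 for IFI44L, 1.27 for AKR1C1, -1.22 for IRF9, 0.85 for TIMP3 and 3.51 for GPNMB, past the threshold, and did not pass for IFITM1 (-0.24), AQP1 (-0.87), IFI27 (-0.84) or TDO2 (0.65).

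Single arrays lay far from the other 3 of their group in 15 of 164 groups of values tested, where chance gives about 8.2. BT-20 CapG replicate 1 had 59.1% of probes well above background and a spatial trend of 16.9, and stood apart for C19orf33 (0.49), SYTL5 (-0.29) and PSAT1 (-3.64). Outlier spots made up 0.187% on BT-20 control replicate 1 and 1.30% on MDA-MB-231 control replicate 1, and the median CV of replicated probes was 7.65% on siCapG replicate 4. CAPG was lowest on siCapG replicate 4, at -0.076. Other such values were C19orf33 at -1.88 on BT-20 control replicate 3, VAV1 at -6.75 on BT-20 control replicate 4, FANCD2 at -8.25 on siCapG replicate 2 and ADAM28 at -3.86 on MDA-MB-231 control replicate 4. The actin turnover mean was 2.19 on siCapG replicate 3 and the TGF-beta target mean -0.11 on siCapG replicate 4.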

How the results depend on the processing

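Alternatives chosen only after the data were seen were the repaired normexp correction, the other combinations with normexp, the combinations of slide block with quantile scaling or with an estimated correlation, the exchange of the BT-20 labels, and the list tests on single slides or without single arrays.

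Of 3827 values of 169 named genes and lists under alternatives, 3430 kept their direction and side of the threshold, 382 lost the call and 15 reversed. Of 178 values of 9 main results, 142 stayed on their side of the threshold or within 1.5 times the count, 5 lost the call and 31 moved further.

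The planned normexp correction failed on 5 arrays (BT-20 CapG replicate 2, MDA-MB-231 control replicates 2 and 4, siCapG replicates 2 and 3). A few spots on bright local background, with signals down to -62764.8 after subtraction, raised the fitted noise SD there to between 106 and 860, against 0.905 to 8.56 on the other 11 arrays. With those spots left out it was at most 4.72. The failed fit is therefore no evidence on stability. For genes changed in BT-20 it gave 67 (74.6% higher, with the median of all genes moved from 0.04 to 0.17), for genes changed in MDA-MB-231 885, for genes whose response differs between the lines 1005, for genes following CAPG in both lines 1, for genes differing between the control lines 6873 and 16 BT-20 lists, and CAPG in BT-20 at -0.57 without a call. With a slide block it gave 13 and 1883 genes, with CAPG again at -0.57, and without the uneven BT-20 array 16 genes and CAPG at -0.58, both without a call. Reversed in BT-20 under the failed fit, with or without slide block, were CCDC63 in BT-20 (0.0095), PCDHB17P (0.11), ADD3 in BT-20 (0.085), ERAP1 (0.46) and AQP1 (0.27). Without the uneven array these were 0.058, 0.21, 0.13, 0.52 and 0.32. None of the 5 reversed under the repaired correction, which gave 3115 genes in BT-20, 2807 of them among the 5252, and 443 following CAPG. The cause of these lower counts was not tested.

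In BT-20, 334 genes passed with at least 2-fold change, 3431 without a filter on dim probes, where more genes are tested, 3236 with a replicate block, 514 with all 16 arrays in 1 fit, where the spread of MDA-MB-231 enters, and 783 on slide 3 and 122 on slide 4, where arrays are fewer. CAPG lost its call on slide 4 alone (-0.61) and with all 16 arrays (-0.63). In MDA-MB-231 there were 3159 with at least 2-fold change, 675 on slide 1, 9307 on slide 2, 8111 with quantile scaling and slide block and 8096 with all 16 arrays. The genes following CAPG in both lines numbered 425 without the filter and 490 with a replicate block. For slide 2, the block settings and the last MDA-MB-231 counts the cause was not tested. In MDA-MB-231, deviations from the group means had a mean correlation of 0.43 between control and siCapG arrays of the same slide. Between arrays of different slides it was -0.41. In BT-20 these means were 0.12 and -0.12, so arrays differed more by slide in MDA-MB-231. Numbers do not pair the arrays, so the replicate block has no basis in the design.

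With an estimated correlation 0 lists passed in BT-20 and 8 in MDA-MB-231, and with slide block also 0 and 4 (cell cycle, DNA replication, actin turnover and interferon-stimulated genes). In BT-20 quantile scaling gave 5 lists and fry, which does not compare a list with other genes, 21.

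Leaving out each array gave 3360 to 6589 genes changed in BT-20, lowest without control replicate 1, 3612 to 6913 genes changed in MDA-MB-231, 4904 to 8334 genes whose response differs between the lines, 513 to 870 genes following CAPG in both lines and 12834 to 13882 genes differing between the control lines. The range was -0.67 to -0.58 for CAPG in BT-20 and -4.94 to -4.61 for CAPG in MDA-MB-231. Lists numbered 3 without BT-20 CapG replicate 1 and 20 without MDA-MB-231 control replicate 4. Signal over background limits dim genes, of which 114 called in BT-20 and 120 in MDA-MB-231 were well above background on no array of the dimmer group.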

Other observations

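The motile cilium test was chosen after the result was seen, and the seed tests were not.

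Several genes of motile cilia stood among the largest increases in siCapG cells, such as RSPH1, part of the radial spoke, at 3.48. A list of motile cilium genes without the 6 noticed ones was then tested. Of 58 genes 19 rose and 4 fell (22 and 5 when adjusted over the list alone), with a median of 0.55, and the limma camera p was 0.00069, or 0.0067 with an estimated correlation. ROPN1L rose by 2.68 and OSCP1 by 2.69, while DNAH12 fell by 2.57. This is consistent with a rise of the class, a hypothesis found and tested on the same arrays. In BT-20, 10 of 53 rose and 8 fell (10 and 8 when adjusted over the list alone), with a camera p of 0.33.

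Genes whose probes carry a match to the seed of the siRNA could fall through off-target silencing. For the guide strand 87 probes with GTCAGCA had a median of -0.00025, at percentile 15.4 among 422 heptamers of the same composition. For the passenger strand the 71 probes were at percentile 17.1 among 35 heptamers. Probes cover only part of each transcript, so off-target silencing stays open.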
